A study of Mus musculus with 6 samples.

How the data were processed

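RNA sequencing was used to measure gene expression in microglia of the adult mouse brain in 6 libraries, 3 from Mir137 conditional knockout mice (cKO) and 3 from their Cre-carrying controls (cWT). The groups were taken from the sample titles. The labels name 3 replicates per genotype and 4 mice in the isolation of microglia, without saying how the mice fall into the replicates. The p-values therefore measure only the spread between these samples, which may be technical. No batch, date or library kit is named in the labels, and the way microglia were purified is not given in the sources used here beyond their isolation.

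The authors deposited a table of estimated counts, with 1 column per library and 1 row per gene symbol, not scaled between libraries. STAR 2.7.9a, RSEM and DESeq2, with the genome builds GRCm38 and mm10, are named in the submitters' processing notes with no role or order, and the annotation and the strand setting are not given in the sources used here. Between 5.5% and 5.85% of the values in a column were not whole numbers, so they were taken for estimates and rounded to whole numbers before testing. All 17459 symbols of that table matched a row of a second table, the authors' own comparison of cKO with cWT. That deposited table gives a base mean, a signal averaged over the libraries after scaling, per the file headers. It also gives a log2 fold change with its standard error, per the file headers. The deposited Wald statistic is a score, the log2 fold change over its standard error. The deposited p-values and adjusted p-values are DESeq2 result columns per the file headers, and the method of adjustment is not stated there.

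Total counts per library ranged from 16503817 to 17482042 in cWT and from 12068698 to 15212806 in cKO. The floor of 3 counts used to bound a fold against 0 covers counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a genotype differed by more than counting noise, with chi-square values per degree of freedom from 3.84 to 19.3, so no library was counted as a duplicate of another.

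Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling, robust dispersion estimation and genotype as the only term. Genes with low counts were removed by filterByExpr with a minimum count of 10, which left 13490 genes and set aside 3969. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. CPM values are counts scaled to a common library size, with the TMM factors applied. Standard errors of log2 fold changes were derived from the test statistic. Of 38 gene lists, the 36 with at least 5 tested members were compared with the remaining genes by camera from limma 3.58.1, with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The lists, the tests and the alternatives to them were fixed before the data were examined, with exceptions. These were the offsets, the thinning, and the random lists matched on transcript length for the miR-137 sites, described below. Tests chosen later are also named under the other observations.

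The genes named were chosen by a fixed rule. It always took Mir137, Tmem119 and Jdp2. It then took the 10 largest increases and the 10 largest decreases among called genes with an average log2 CPM of at least 2 and no overlap between the genotypes, leaving out predicted genes named by number, Rik genes and pseudogenes. The 5 most abundant genes called in each direction were added, and the 3 members with the smallest p of each list that was called or held at least 3 called members. Xist and 4 genes of the Y chromosome served as a check of the labelled sex. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

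Transcript lengths, GC content, 3' UTRs and coordinates were taken from GENCODE and RefSeq annotation of GRCm38, the build in the submitters' processing notes. A length was found for 12983 tested genes (96.2%), from the principal transcript where the annotation marks 1. That transcript need not be the one expressed. Olfml3, for example, has a length of 5465 bases, while its RefSeq coordinates run from 103735394 to 103738001. Offset values of single genes hold only as far as their annotated length does. Sites matching the miR-137 seed were searched in the longest annotated 3' UTR of each gene as the sequence AGCAATA, and as AGCAATAA for the stricter site. Genes without an annotated 3' UTR were left out of that test. Genes with a site were compared with other genes by camera, and their median with that of 10000 random lists matched on 3' UTR length and mean expression.

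The alternatives fixed in advance were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, non-robust dispersion, a replicate block, leaving out each library in turn, and leaving out ribosomal protein, mitochondrial and haemoglobin genes. Chosen after seeing the data were per-library offsets and thinning all libraries to the smallest total. The offsets reduce the trend of log2 CPM with transcript length and GC content, by splines with 4 degrees of freedom. The offsets were tested on simulated data of 13490 genes with a length trend and 200 changed genes on top of it. There 7612 genes were called without offsets and 196 with them. Of the changed genes that could be tested with offsets, 96.3% were recovered. All changed genes were given the same size of change. The simulated trend was built from the same annotated lengths that the offsets use, with no trend in GC content. The simulation therefore does not show how well the offsets work where annotated lengths are wrong, or how many calls in the real data are right.

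The edgeR steps were tested on counts simulated for the comparison of cKO with cWT over the 13490 genes. Of 50 genes changed at each size, 58% were recovered at 1.5-fold, 80% at 2-fold, 94% at 4-fold and 96% at 8-fold, and 11 of 175 calls were false. The matched comparison of seed-site genes was tested on simulated data with a length trend and no effect of the sites, where the median of the site genes fell by 0.032 against the matched lists (permutation p = 0.036, random lists). Matching on 3' UTR length thus left part of a trend with transcript length in place.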

Results

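Microglia are the resident macrophages of the brain. Here they came from male C57BL/6J mice aged 8 weeks in which miR-137, a microRNA best known from neurons, had been removed from microglia. The cKO mice carried loxP-flanked Mir137 alleles and a Cre recombinase that tamoxifen activates, expressed from the microglial gene Tmem119. The cWT mice carried the same Cre with intact Mir137. Tamoxifen was given on 7 days at 7 to 8 weeks of age. Gene expression was measured by RNA sequencing in 3 cKO and 3 cWT libraries. The cWT libraries held 16503817, 16734743 and 17482042 estimated counts, and the cKO libraries 12068698, 12562367 and 15212806.

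Mir137 itself (chromosome 3, 118433857 to 118433929, GRCm38) had a base mean of 0 in the authors' deposited table, and its level per library was not analysed here, so the deletion was not checked from these values. Tmem119, the gene that drives the Cre (chromosome 5, 113793729 to 113800396), rose from 425 ± 30.1 CPM in cWT to 1084 ± 225 CPM in cKO (SD, n = 3 each), a log2 fold change of 1.35 (SE 0.13, edgeR adjusted p = 4.763e-08). Whether the Cre allele alters that locus, and its copy number in each genotype, are not given in the sources used here, so this level need not be that of an intact gene. Jdp2, a repressor of the AP-1 transcription factor family (chromosome 12, 85598656 to 85639878), rose from 16.9 ± 1.89 to 44.4 ± 3.48 CPM, a log2 fold change of 1.39 (SE 0.12, adjusted p = 9.447e-09), which stood at 0.80 with offsets for transcript length and GC content, described below. Xist counts lay between 0 and 3 in each library, and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were measured in both genotypes, with 12.2 ± 1.85 CPM for Kdm5d in cKO as the lowest mean.

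The comparison of cKO with cWT asks what the loss of miR-137 changes in microglial transcripts. Genes of mitochondrial respiration and the cytosolic ribosome were higher in cKO throughout, as were the lysosomal and secreted microglial proteins Cst3, Ctsd, Ctss and C1qb. Chromatin regulators such as Kmt2d and Arid1a, the microglial receptor Cx3cr1 and the microglial transcription factor Sall1 were lower. These changes go with a trend of fold change with transcript length, described below, and are smaller once offsets reduce it. Cst3, which encodes the protease inhibitor cystatin C, was the most abundant gene in each library and went from 17140 ± 2014 to 67514 ± 7695 CPM (n = 3 each). Its log2 fold change was 1.98 (SE 0.14, adjusted p = 7.387e-10), and its share of all counts went from 1.96% ± 0.218 to 5.88% ± 0.512.

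Of 13490 genes tested, 9729 (72.1%) were called, 4803 that rose and 4926 that fell. A change of at least 2-fold was called for 5214 of them, 2567 higher and 2647 lower. The genotypes did not overlap for 10065 genes (74.6%), where chance gives 10%. The leading principal component held 84.2% of the variance. Spearman correlations across genes, which are not independent replicates, were 0.987 to 0.996 between libraries of the same genotype and 0.867 to 0.884 between genotypes. When libraries were scaled by total count alone, the median log2 fold change of all genes moved from -0.02 to -0.42, and 33.1% of the calls were increases (3331 against 6742), compared with 49.4% with TMM scaling. Fold changes are reported relative to the TMM scale.

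Log2 fold changes followed transcript length. Among the 12983 genes with a known length, the Spearman correlation across genes was -0.72. In the shortest of 10 equal groups of genes, with transcripts of 174 to 1222 bases, the median log2 fold change was 1.57, and 86.2% of the genes rose while 2.69% fell. In the longest group, from 6456 bases upward, the median was -1.45, with 3.08% higher and 83.2% lower. Within libraries, log2 CPM correlated with length at 0.181 ± 0.00353 in cWT and -0.154 ± 0.0126 in cKO (Spearman, mean ± SD, n = 3 each). For this reason each list that was called is given with its median transcript length and with its value under offsets for length and GC content. The plot of list medians shows the offset values of all lists tested. The offsets reduced the trend without removing it, and a Spearman correlation of -0.081 between log2 fold change and length was left. With the offsets 7413 of 12983 genes were called, 3824 higher and 3589 lower, and 2025 of them changed by at least 2-fold. Of 9381 genes called without offsets and tested again, 5372 were called in the same direction and 619 in the opposite direction.

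**Figure D1:**
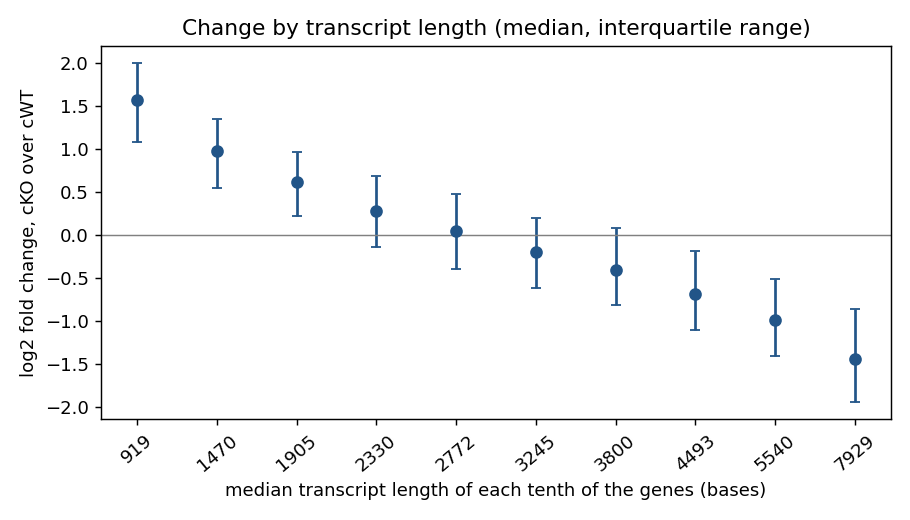
Log2 fold change of cKO over cWT (vertical axis) for 10 equal groups of genes ordered by transcript length, with the median length in bases of each group on the horizontal axis. Points are medians and bars run from the lower to the upper quartile over genes; the medians fall from 1.57 in the shortest group to -1.45 in the longest.

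Ifi202b, an interferon-inducible member of a gene cluster with close paralogs (chromosome 1, 173962569 to 173982844), had counts of 329, 348 and 217 in the cKO libraries and 0 in each cWT library. Against a floor of 3 counts per library it was at least 171-fold higher in cKO. Reads shared with its paralogs make its level uncertain. The next largest increases were those of Serpina3n, an acute-phase protease inhibitor, with a log2 fold change of 6.32 (SE 1.17, adjusted p = 0.007564), and of Saa3, an acute-phase apolipoprotein, with 5.52 (SE 0.95, adjusted p = 0.003983). Serpina3n varied widely among the cKO libraries (25.4 ± 21.3 CPM, n = 3). Plac9a, Plet1os, Cox8b, LOC100861615, Wfdc17, Apod and Ifitm1 rose by log2 fold changes between 3.88 and 5.43. Plet1os is an antisense gene, whose counts cannot be told from those of its partner where strand was not used.

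Hbb-bs, a beta-globin gene (chromosome 7, 103826523 to 103827928), had counts of 450, 458 and 123 in cWT and 0 in each cKO library, at least 68.2-fold lower against the floor of 3 counts per library (edgeR adjusted p = 0.03441). Its reads are shared with near-identical paralogs, and its call was lost without cWT replicate 1 or 2 or cKO replicate 1 or 3, with adjusted p from 0.0504 to 0.0866, and with no filter on low counts (adjusted p = 0.0594). Egr3, an immediate early transcription factor, fell by 5.25 on the log2 scale (SE 0.44, adjusted p = 6.348e-09), from 6.92 ± 0.73 to 0.186 ± 0.162 CPM. Hivep3, a large zinc finger protein, fell by 4.41 and the histone methyltransferase gene Kmt2d by 3.83 (SE 0.11, adjusted p = 1.391e-13). Setd1b, Fat4, Crebbp, Adnp, Spen and Cyyr1 fell, with log2 fold changes from -3.49 to -3.26. With the offsets Kmt2d stood at -1.58, Hivep3 at -2.61 and Egr3 at -4.77.

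Among the most abundant genes, Ctsd, which encodes a lysosomal protease, rose by a log2 fold change of 0.90, the protease gene Ctss by 1.48 and the complement gene C1qb by 1.60. Csf1r, the receptor for the survival factor CSF1, went from 8953 ± 726 to 5316 ± 567 CPM, a log2 fold change of -0.75 (SE 0.12, adjusted p = 2.096e-05). Cx3cr1, the fractalkine receptor, fell by 1.29, Serinc3 by 0.72, Mpeg1 by 0.46 and Fcrls by 0.38, the last with no call when cKO replicate 2 was left out (adjusted p = 0.127). With the offsets Csf1r and Mpeg1 were not called, at 0.11 and 0.044, while Cx3cr1, Serinc3 and Fcrls were still lower at -0.63, -0.55 and -0.79. Of the genes that rose, Cst3, Ctsd, Ctss and C1qb stood at 0.70, 0.63, 0.33 and 0.55 with the offsets.

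**Figure D2:**
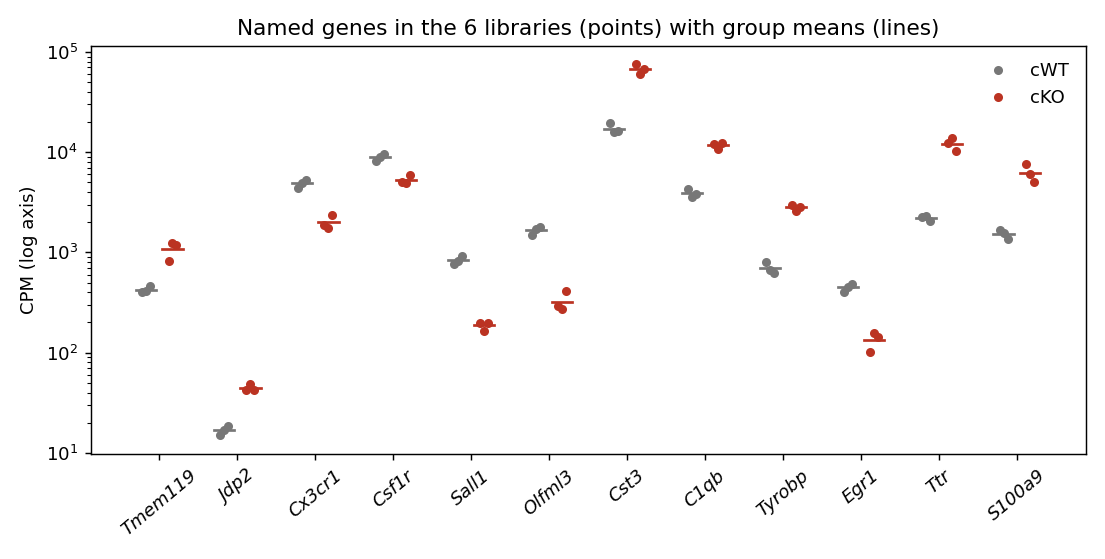
Expression of 12 named genes in CPM (vertical log axis) in the 3 cWT and 3 cKO libraries. Points are libraries and short lines are group means; Tmem119 stands at 425 CPM in cWT and 1084 CPM in cKO, and Csf1r at 8953 and 5316 CPM.

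Genes of the homeostatic microglial state moved in both directions, 8 of 25 up and 10 down (median -0.07, camera adjusted p = 0.623). Olfml3, a secreted glycoprotein typical of microglia, fell by 2.37 and Sall1, a transcription factor that maintains microglial identity, by 2.16, whereas the crystallin gene Crybb1 rose by 1.75. With the offsets Olfml3, Sall1 and Crybb1 stood at -1.39, -1.25 and 0.63. Of 25 genes of disease-associated microglia, 16 rose and 5 fell (median 0.90, adjusted p = 0.021, and adjusted p = 0.273 with an estimated correlation). Tyrobp, the adaptor of TREM2, rose by 2.01, the tetraspanin Cd63 by 1.91 and the chemokine Ccl6 by 1.59. The transcripts of this list are short, with a median of 1440 bases, and with the offsets its median was 0.14 (adjusted p = 0.752).

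Of 28 type I interferon response genes, 17 rose and 7 fell (median 0.57, adjusted p = 0.0275, and adjusted p = 0.774 with an estimated correlation). Ifi27l2a rose by 3.08, Xaf1 by 1.85 and Bst2 by 1.72. The transcripts of the list have a median of 2488 bases, and with the offsets it stood at 0.29 (adjusted p = 0.167). Xaf1, Ifi27l2a and Bst2 were then at 1.61, 1.17 and 0.30. Inflammatory cytokine and NF-kB response genes were split, with 13 of 29 up and 10 down (median 0.15, adjusted p = 0.419). Cxcl2, a chemokine for neutrophils, rose by 2.61, the endotoxin co-receptor Cd14 by 1.52 and the cytokine Il1b by 1.45. This list turned with the offsets, to a median of -0.50 (adjusted p = 0.0242, and adjusted p = 0.695 with an estimated correlation). Antigen presentation genes were not called as a list, with 10 of 20 up and 5 down (median 0.42, adjusted p = 0.107, and adjusted p = 0.0497 without cKO replicate 2); H2-T23, Psmb8 and H2-DMb1 rose by 1.64, 1.57 and 1.27.

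Immediate early genes were lower in cKO, with 13 of 25 down and 4 up (median -0.32, adjusted p = 0.046, and adjusted p = 0.781 with an estimated correlation). Besides Egr3, Fosb fell by 2.32 and Egr1 by 1.75. These genes are also induced when tissue is dissociated into cells. With the offsets the median of the list, whose median transcript has 2553 bases, was -0.55 (adjusted p = 2.25e-05, and adjusted p = 0.676 with an estimated correlation). The call of the list was lost without cWT replicate 3 (adjusted p = 0.052), without cKO replicate 1 (adjusted p = 0.0777), with a filter of at least 5 CPM in 3 libraries (adjusted p = 0.0736) and without mitochondrial, ribosomal protein and haemoglobin genes (adjusted p = 0.0501). In the AP-1 family, which shares members with that list, 9 of 18 genes fell and 4 rose (median -0.63, adjusted p = 0.183), with Atf7 lower by a log2 fold change of -2.25 and Jdp2 higher.

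Of 25 lysosomal genes, 19 rose and 3 fell (median 0.61, adjusted p = 0.0242, and adjusted p = 0.781 with an estimated correlation). Ctsz and Ctsl, which encode cathepsins, rose by 1.39 and 1.31, and the cholesterol transporter Npc1 fell by 1.26. With the offsets the list was still higher, at 0.32 (adjusted p = 0.00338, and adjusted p = 0.695 with an estimated correlation), with a median transcript of 2340 bases. With libraries scaled by total count alone its median was 0.22 and it was not called (adjusted p = 0.0851). Complement and phagocytosis genes were split, 9 of 24 up and 9 down (median 0.05, adjusted p = 0.419), with C1qa up by 1.53 and the inhibitory Fc receptor Fcgr2b by 1.40. Cholesterol synthesis genes were also split, 8 of 23 up and 8 down (median -0.04, adjusted p = 0.794), where Srebf2 fell by 1.56 and Ebp rose by 1.09. Of 15 LXR targets, 10 fell and 3 rose (median -0.71, adjusted p = 0.0552), among them Fasn at -1.69, Abca1 at -1.64 and Abca7 at -1.63. None of these 3 LXR targets was called with the offsets (0.10, -0.16 and -0.19), and the median of the list was then 0.06. The LXR list was called without cWT replicate 1, cKO replicate 2 or cKO replicate 3 (adjusted p = 0.0441, 0.0492 and 0.0346).

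All 38 oxidative phosphorylation genes rose (median 1.96, adjusted p = 4.51e-27, and adjusted p = 0.219 with an estimated correlation), among them Ndufa2 by 2.57, Cox4i1 by 2.23 and Cox8a by 2.05. All 82 tested genes of cytosolic ribosomal proteins rose as well (median 2.16, adjusted p = 9.9e-49, and adjusted p = 0.252 with an estimated correlation), with Rpl36 up by 2.54, Rps9 by 2.44 and Rps15 by 2.28. Transcripts of these lists are short, with medians of 824 and 882 bases. With the offsets 33 of 38 and 73 of 82 genes rose, and the medians were 0.57 (adjusted p = 3.75e-07, and adjusted p = 0.496 with an estimated correlation) and 0.67 (adjusted p = 9.99e-21, and adjusted p = 0.676 with an estimated correlation). Many ribosomal protein genes have processed pseudogenes that share their reads. Of 30 chromatin regulators, 25 fell and 4 rose (median -1.72, adjusted p = 1.75e-13, and adjusted p = 0.219 with an estimated correlation). Kmt2a and Arid1a, parts of a methyltransferase and a remodelling complex, fell by 3.20 and 2.97. Their transcripts are long, with a median of 6402 bases, and with the offsets the list stood at -0.52 (adjusted p = 3.93e-06, and adjusted p = 0.515 with an estimated correlation).

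Of 15 genes of the small RNA machinery, 11 fell and 3 rose (median -1.32, adjusted p = 0.00534, and adjusted p = 0.252 with an estimated correlation). The microRNA-binding genes Ago2 and Ago1 fell, with log2 fold changes of -2.78 and -1.63, and Dicer1, which cuts microRNA precursors, fell by 2.02. The list has a median transcript of 6537 bases and stood at -0.18 with the offsets (adjusted p = 0.391). In the TGF-beta pathway 14 of 21 genes fell and 4 rose (median -0.92, adjusted p = 0.0293, and adjusted p = 0.252 with an estimated correlation). Smad3, a signal transducer, fell by 2.21 and Ski, a repressor of the pathway, by 1.88, whereas the target Id1 rose by 1.66. With the offsets this list, of median transcript length 4278 bases, stood at -0.27 (adjusted p = 0.178), and it was not called with a filter of at least 5 CPM in 3 libraries (adjusted p = 0.055). Of 21 oxidative stress genes, 11 rose and 4 fell (median 0.71, adjusted p = 0.0406, and adjusted p = 0.252 with an estimated correlation). Sod1, Cyba and Txn1 rose by 1.91, 1.73 and 1.71. That list stood at 0.15 with the offsets (adjusted p = 0.207), with a median transcript of 2652 bases, and lost its call without cWT replicate 1 (adjusted p = 0.053), with that filter (adjusted p = 0.0691) and with library size alone (median 0.31, adjusted p = 0.0933).

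The remaining pathway lists were not called. Glycolysis had 12 of 19 genes up and 4 down (median 0.47, adjusted p = 0.183), with Tpi1, Ldha and Pgk1 up by 1.26, 1.19 and 1.09, and with the offsets it was called at a median of 0.45 (adjusted p = 0.0469, and adjusted p = 0.515 with an estimated correlation). Unfolded protein and stress response genes had 10 of 20 up and 3 down (adjusted p = 0.176), with Ddit4, an inhibitor of mTORC1, up by 2.54, Sdf2l1 up by 1.39 and Sel1l down at -1.41. Targets of p53 had 7 of 17 up and 5 down (adjusted p = 0.419), with Fas up by 1.98, Bax by 1.67, and Zmat3 at -1.72. Hypoxia genes had 6 of 16 in each direction (adjusted p = 0.419), with Ankrd37 and Bnip3 up by 2.37 and 1.29. Proliferation genes had 6 of 26 up and 10 down (adjusted p = 0.794), where Mki67 fell by 1.77 while Tyms and Pcna rose by 1.58 and 1.28.

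Adjusted over the list alone, the counts were the same except in 7 lists. Disease-associated genes then had 6 down, immediate early genes 3 up, lysosomal genes 20 up, proliferation genes 5 up, oligodendrocyte markers 10 up, endothelial markers 9 down and erythroid markers 0 down. In all, 12 of 36 lists were called by camera, 7 higher and 5 lower. With an estimated correlation camera called 0 lists, with 5 at an unadjusted p under 0.05, and fry called 30.

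**Figure D3:**
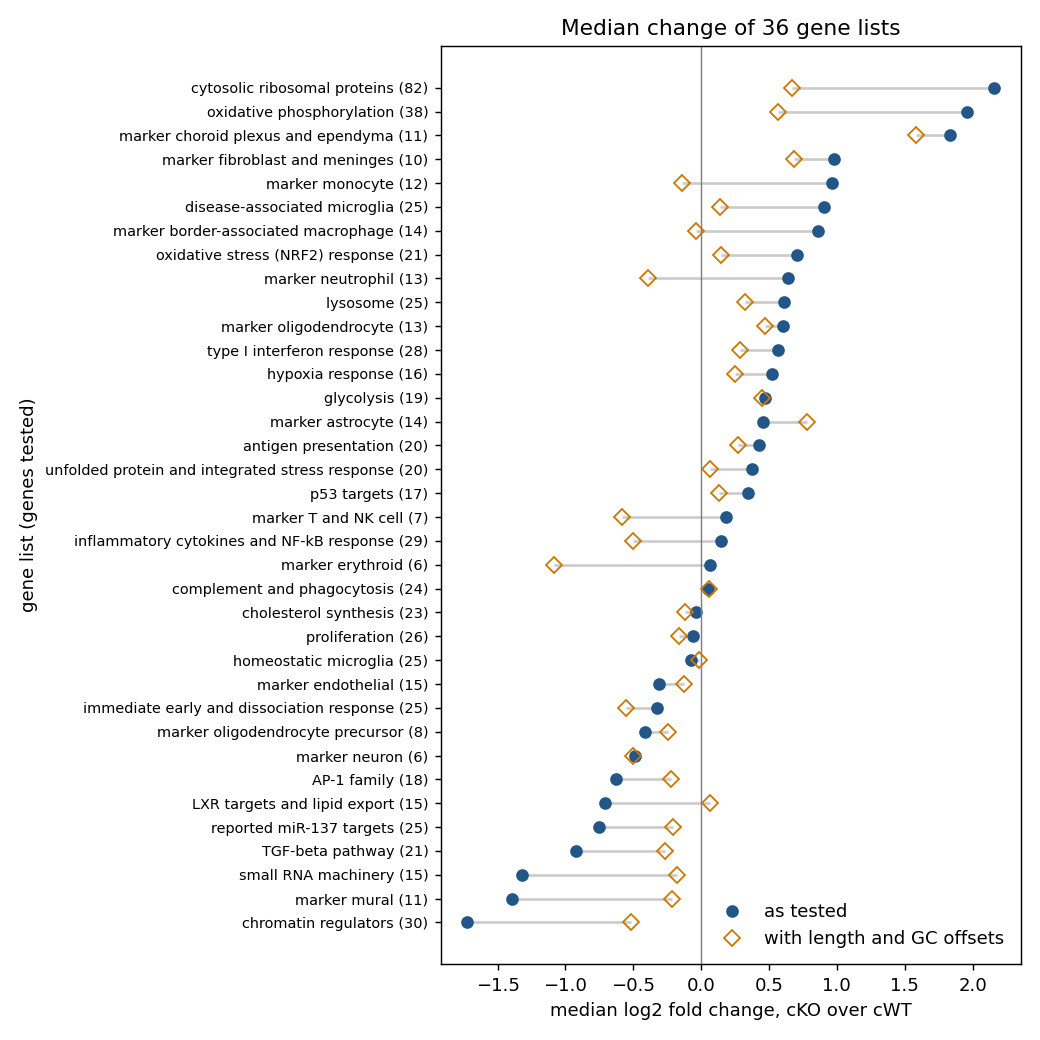
Median log2 fold change of cKO over cWT (horizontal axis) for 36 gene lists (vertical axis, with the number of genes tested). Filled circles are values as tested and open diamonds values with offsets for length and GC content; cytosolic ribosomal proteins move from 2.16 to 0.67 and chromatin regulators from -1.72 to -0.52.

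Markers of other cell types were measured to see what else the libraries held. All 11 markers of choroid plexus and ependyma rose (median 1.83, adjusted p = 5.35e-05, and adjusted p = 0.252 with an estimated correlation). Ttr, the transthyretin gene of the choroid plexus, went from 2216 ± 130 to 12112 ± 1816 CPM (n = 3 each), a log2 fold change of 2.45 (SE 0.13, adjusted p = 2.63e-11). Ccdc153 rose by 3.74 and Folr1 by 1.90. The median transcript of this list has 1313 bases. With the offsets 10 of the 11 genes rose, at a median of 1.58 (adjusted p = 1.18e-05, and adjusted p = 0.515 with an estimated correlation). Neutrophil markers had 7 of 13 up and 4 down (median 0.64, adjusted p = 0.176), with Retnlg, S100a8 and S100a9 up by 2.23, 2.05 and 2.01. With the offsets the neutrophil median was -0.39 (adjusted p = 0.11), and S100a8 and S100a9 stood at -0.048 and -0.036.

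No other marker list was called. Oligodendrocyte markers had 9 of 13 up and 2 down (adjusted p = 0.183), led by Mog at 2.26, Opalin at 2.21 and Mal at 1.28. Astrocyte markers had 6 of 14 up and 1 down (adjusted p = 0.27), with S100b, Clu and Cpe at 1.88, 1.16 and 1.10, and with the offsets 11 up and 0 down (median 0.78, adjusted p = 0.0979). Fibroblast and meningeal markers had 7 of 10 up and 3 down (adjusted p = 0.193), with Ptgds at 2.98 and Igfbp2 at 1.57, and Vcam1 also higher. Endothelial markers had 4 of 15 up and 8 down (adjusted p = 0.152, and adjusted p = 0.0491 without cWT replicate 3), where Ly6c1 rose by 1.95 while Ptprb and Flt1 fell by 2.19 and 2.16. Mural markers had 4 of 11 up and 6 down (adjusted p = 0.259), with Tagln at 1.58, Notch3 at -2.69 and Cspg4 at -2.47. Border-associated macrophage markers had 8 of 14 up and 4 down (adjusted p = 0.572), with Clec10a at 1.68, Dab2 at -1.86 and Stab1 at -1.80. Monocyte markers had 7 of 12 up and 3 down (adjusted p = 0.296), with Hp at 1.59, Ly6c2 at 1.37 and Fn1 at -2.07.

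The remaining marker lists had at most 8 tested genes each. Neuronal markers had 1 of 6 up and 2 down (adjusted p = 0.784), with Stmn2 at 0.59, Camk2a at -1.80 and Meg3 at -2.20, and with the offsets 0 of the 6 were called. Stmn2 was also not called with library size alone, at 0.19 (adjusted p = 0.309). Oligodendrocyte precursor markers had 0 of 8 up and 2 down (adjusted p = 0.55), T and NK cell markers 1 of 7 up and 0 down (adjusted p = 0.651). Erythroid markers had 0 of 6 up and 1 down (adjusted p = 0.79), with a median of 0.07, a mean of -1.63 and a lower direction in the test; the mean depends on the fitted fold of Hbb-bs against 0, and the median is the same with Hbb-bs at its bound. The B cell list had 4 tested genes, 1 up and 1 down, too few to test. The list of mitochondrially encoded genes had 0 genes to test here.

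A microRNA lowers mRNAs that carry its seed sites, so the comparison of genes with and without a miR-137 site addresses its direct targets. Genes with a site were lower in cKO than other genes, with medians of -0.53 over 1357 genes and 0.03 over 11260 genes, a difference of -0.56 (limma camera, adjusted p = 4.24e-05 over 3 such tests, and adjusted p = 0.117 with an estimated correlation). Random lists matched on 3' UTR length and expression had a median of -0.47, and the site genes differed from them by -0.056 (two-sided permutation p = 0.0922, 10000 random lists, adjusted p = 0.184 over 4 such tests). With lists matched instead on transcript length, 3' UTR length and GC content, and not on expression, the difference from random lists was -0.030 (permutation p = 0.269). The 585 genes with the stricter site lay 0.022 above their matched lists (permutation p = 0.689). The permutation p-values from random lists take genes as independent and measure the spread over genes, not between libraries. With the offsets the difference between genes with and without a site was -0.087 (limma camera, adjusted p = 0.45), and that from matched lists was -0.036 (permutation p = 0.0392, adjusted p = 0.157). Of 25 tested genes reported as miR-137 targets in other settings, 16 fell and 4 rose (median -0.75, adjusted p = 0.0293, and adjusted p = 0.252 with an estimated correlation). Mib1 fell by 2.13, Ncoa2 by 1.95 and Tcf4 by 1.32. With the offsets Tcf4 was not called, at -0.16 (adjusted p = 0.1026), and this list, of median transcript length 3766 bases, stood at -0.20 (adjusted p = 0.11).

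The authors' deposited table of cKO against cWT lists 24411 genes, 16374 of them with an adjusted p. At an adjusted p under 0.05 the authors' deposited table has 4775 genes higher and 4698 lower in cKO. For Tmem119 and Jdp2 the authors' deposited table gives log2 fold changes of 1.35 and 1.40. Across the 13490 genes tested from the counts, the Spearman correlation of its fold changes with those from edgeR was 0.99998, a description across genes of 2 fits to the same libraries. The authors' deposited table and the edgeR test shared 9258 called genes, and 9258 of them had the same direction.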

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

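Offsets for transcript length and GC content and thinning to equal totals were chosen after seeing the data, and the cause of the changes below was not tested beyond what the settings themselves change. The number of called genes stayed within 1.5 times under each alternative run, from 9116 to 9717 (4518 to 4842 higher, 4597 to 4875 lower) when a library was left out, and genes changed by at least 2-fold from 5136 to 5326. Only the offsets moved the latter beyond that, to 2025. Camera called 11 to 14 lists without a library (6 to 8 higher, 4 to 6 lower). It called 0 lists in either direction with an estimated correlation, and 3 lower with at least 5 CPM in 3 libraries or with the offsets. Fry called 30 lists (19 higher, 11 lower). The site difference of miR-137 ranged from -0.57 to -0.50 without a library and was -0.087 with the offsets. The excess over matched lists ranged from -0.068 to -0.037 without a library. Its permutation p was under 0.05 without a filter on low counts (-0.079), without cKO replicate 1 (-0.068) and with the offsets (-0.036). For the stricter site the excess was 0.022, with a permutation p of 0.689.

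With the offsets the log2 fold change changed sign for Csf1r (0.11), Mpeg1 (0.044), Fasn (0.10), Stmn2 (-0.014), Ly6c2 (-0.19), S100a8 (-0.048), S100a9 (-0.036), Eif2s3y (-0.47), Uty (0.19) and Kdm5d (0.038). List directions turned with the offsets for inflammatory cytokines (median -0.50), antigen presentation (median 0.27, with camera lower), border-associated macrophages (-0.035), monocytes (-0.14), neutrophils (-0.39) and T and NK cells (-0.58). With library size alone the camera direction turned for proliferation (median -0.45), neuronal (-0.88) and erythroid (-0.32) lists, and without cKO replicate 3 for the erythroid list (-0.52, range to 0.12 over the libraries left out), none of them called. A replicate block gave 9911 called genes (4883 higher, 5028 lower), and with it camera also called antigen presentation and neutrophil markers (adjusted p = 0.0425 each). With library size alone (adjusted p = 0.0341) or no filter on low counts (adjusted p = 0.0193) the LXR list was called. Same-numbered libraries deviated together with correlations of 0.0985, 0.0335 and 0.0882, none above 0.1, so they are treated as sharing only a number. Even so, 6 of 6 libraries correlated best with their own number. The same correlations were read from the side of each genotype, so these 6 results are not independent. They are a weak hint from the data and not the design. Small changes can be missed: at the depths of these libraries, the smallest with 12068698 counts, 58% of simulated 1.5-fold changes were recovered. That simulation gave 175 calls against 9729 here, so its Benjamini-Hochberg cut-off on p was stricter. Its recovery therefore need not be that of the real comparison.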

Other observations

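Chosen after the results were seen were the genes of the next 2 paragraphs, the offsets and the thinning of libraries. So were the tests of the choroid plexus and neutrophil lists on their own, and the comparison of Ifi202b and Hbb-bs with genes of their length. For the choroid plexus and neutrophil lists on their own, a larger share was read only where all longer members lay on the same side, a stricter rule than for both lists together. The comparison of genes with a miR-137 site to lists matched on transcript length was not fixed in advance either. The remaining tests were set out before their results were seen.

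Within the immediate early list the falls were graded. Fos fell by 0.98 (SE 0.11, adjusted p = 4.257e-07), Nr4a1 by 1.44 and Egr2 by 2.03, while Jun at -0.18 and Junb at -0.14 were not called (adjusted p = 0.2045 and 0.3244). With the offsets Fos, Nr4a1 and Egr2 stood at -1.41, -1.41 and -1.96. The transcription factor Mef2c, which restrains microglial activation, fell by 1.38 and stood at -1.65 with the offsets, and the long nuclear RNA Malat1 fell by 2.58 and stood at -1.58.

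The class I genes H2-K1 and H2-D1 rose by 0.98 and 1.04, and Cd74, the invariant chain of class II, fell by 1.18. Class II genes did not all move together. H2-Aa was at -0.20 (adjusted p = 0.1271), H2-Ab1 at -0.12 (adjusted p = 0.2804) and H2-Eb1 at -0.22 (adjusted p = 0.03869). Ciita was at -2.74 without offsets (adjusted p = 2.531e-08), while H2-DMb1 and H2-DMa rose by 1.27 and 0.75. With the offsets Cd74 and H2-Aa stood at -1.97 and -1.43 and were both called. Trem2 rose by 1.51 and Apoe, a lipid carrier, by 0.97, and with the offsets they stood at 0.46 and 0.27. Ctsl, with an annotated transcript of 6168 bases, and Fcgr2b, with 3544 bases, rose, whereas the median gene of such a length fell. With the offsets they stood at 2.23 and 1.60, which holds only if the expressed transcripts have these lengths. Gfap, an astrocyte filament gene, rose by 2.33, with 35.1 ± 17.8 CPM in cKO (n = 3).

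The trend of fold change with transcript length was also present among 116 markers of other cell types (Spearman -0.633 across genes). Its permutation p was 1e-05, the smallest that 100000 permutations can give, and measures the spread over genes, not between libraries. Where the Cre was active, and which cells gave these reads, was not measured. Only if the reads came from cells without active Cre do they argue against a microglial response as the whole cause. A difference in RNA integrity or library preparation between the genotypes would give the same correlation. With no such label, genotype and preparation are confounded here. GC content did not account for the trend, since the correlation with length at fixed GC was -0.736. Depth did not either, since the correlation was -0.726 and 9529 genes were called after thinning. Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes as the real one (9729, itself; highest other 0), and 10 splits are too few for a share under 0.05.

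Markers of choroid plexus and neutrophils together had a median of 0.263 with the offsets (sign-flip permutation p = 0.0766), which decides nothing on the length trend, and their 6 longer members a median of 0.791, above the 0.3 set in advance for a larger share of these cells in cKO libraries. The lists then parted. The choroid plexus list kept a median of 1.58 with the offsets (sign-flip permutation p = 0.00108). That p takes choroid plexus and ependymal genes as independent and measures the spread over genes, not between mice. Camera with an estimated correlation gave an adjusted p of 0.515. The median, with 10 of 11 members called higher, argues against the length trend as the whole cause. Its 3 longer members had a median of 1.18. A larger share of choroid plexus or ependymal RNA in the cKO libraries is therefore a candidate explanation. With the offsets, medians were also above 0 for astrocyte (0.78), fibroblast and meningeal (0.68) and oligodendrocyte (0.47) markers. They were below 0 for neuronal (-0.50), oligodendrocyte precursor (-0.25), mural (-0.21) and endothelial (-0.12) markers. Camera called none of these lists with the offsets. Ttr stood at 12112 CPM in cKO, no member was held by another list (0 of 11), and the labels name no purification gate. The neutrophil list fell to -0.391 with the offsets (sign-flip permutation p = 0.0577), with 3 members called higher and 6 lower. The rule for the length trend asked only for a low median. A fall below 0 meets it without showing that trend to be the whole cause. The 3 longer members of the neutrophil list also had a median of -0.391, between -0.89 and 0.80. That leaves a change in neutrophil share open. No biological explanation was tested for either.

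Ifi202b was counted in the cKO libraries alone and Hbb-bs in the cWT libraries alone. Taken against 3 counts per library in the genotype at 0, the log2 bounds on their fold lay at least 6.437 from the median of the genes of the same length. Both genes were picked for being counted in 1 genotype alone, which sets such a distance in advance. The bounds therefore describe the genes and do not test the length trend. Both lie in clusters whose copies differ between mouse strains, so a segment of another strain carried by 1 genotype may be involved. Of 4 genes counted in 1 genotype with at most 3 counts per library in the other, 3 could be placed and 0% lay within 1 Mb of another, too few to decide. Hbb-b1, a beta-globin gene of another haplotype, rose by 1.14 (SE 0.26, adjusted p = 0.00628). It was counted in both genotypes, with 2123.41 to 2613.15 counts in cWT libraries and 2286.57 to 4028.72 in cKO libraries. Genes as short as Hbb-bs had a median of 1.57, so the length trend alone can give a short gene such a rise. Hbb-b2 was at 0.35 (adjusted p = 0.501), with deposited counts identical to those of Hbb-bt, so it tells nothing of the haplotype.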
